A study of Gallus gallus with 24 samples.

How the data were processed

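RNA was taken from 6 tissues of the adult chicken sickle feather follicle in 2 males and 2 females, one library per tissue and animal, which gave 24 libraries in 12 groups of sex and tissue with 2 libraries each. Sickle feathers are the long curved feathers of the tail. The 4 birds carry the numbers 53 and 68 (males 1 and 2) and 52 and 120 (females 1 and 2) in the labels; the numbering 1 and 2 within a sex follows the order of deposition. Every bird gave all 6 tissues, so the tissues of one sex are paired by animal, whereas the sexes are different animals. The labels' protocols name TRIzol for the extraction and the Illumina TruSeq RNA kit, version 2, on polyadenylated RNA.

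The deposited files hold raw whole-number counts per gene, per the file headers and the values, with 17108 versioned Ensembl gene identifiers in the same order in every file. Per the submitters' processing notes, the tools were STAR 2.4.1d, HTSeq 0.6.0 and edgeR (no version given) with the chicken genome build galGal4. The strand setting, the gene annotation release and any read filters are not given in the sources used here. Counts that overlapping, antisense or near-identical genes share are therefore uncertain. The authors' counts were used as deposited.

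The files do not pair the identifiers with gene names. The reference table used here (25635 rows for the assembly GRCg7b) holds no Ensembl identifier, and 0 of the 17108 identifiers matched it. Gene symbols, chromosomes and the 23 gene lists fixed before the data were examined were therefore not used here, and neither was the ratio of male to female expression for genes on the Z chromosome. Genes are given by identifier. The planned rule for naming genes asked for genes with a symbol. It was kept in its other parts and shortened to at most 2 identifiers per direction in each comparison: adjusted p below the threshold, all libraries of one group above all of the other, a mean of at least 1 CPM in the higher group, largest fold first. For a tissue against the other 5, every library of the tissue had to lie above the mean of each other tissue. For the interaction the smallest p decided. In the comparisons of the sexes within a tissue, female-limited genes (below) were passed over for naming, a choice made after the values were seen.

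Differential expression was tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (estimateDisp, glmQLFit, glmQLFTest) on the counts, with TMM normalization and the filterByExpr filter (minimum count 10), which kept 14077 genes and left out 3031, together 0.00878% of all counts. One model with a mean for each of the 12 groups was fitted to the 24 libraries, with 12 residual degrees of freedom. From it came the difference between the sexes in each tissue, the F test for a sex difference that differs between tissues, each tissue against the mean of the other 5, and 3 pairs of tissues. The sex difference over all tissues was tested on 4 sums of counts, one per animal, with 14576 genes and 2 residual degrees of freedom, since the animal is the replicate. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Some counts of genes at an unadjusted p under 0.05 are also given. If no gene differed, a share of 0.05 of the genes tested would be expected there by chance. Such a count shows no excess unless it is above that share. Log2 fold changes are given with standard errors computed from the F statistic, and levels as CPM, the counts scaled to a common library size with TMM factors, with the SD over libraries. Principal components and Spearman correlations used log2 CPM with a prior count of 2.

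Several gene sets were defined after the data were examined. Female-limited genes were those whose lowest CPM among the 12 female libraries exceeded 5 times the highest CPM among the 12 male libraries. Collar-restricted genes, set in the males alone, had more than 50 CPM in both male collar libraries and more than 20 times the level of every male library of the sheaths, pulp and dermal papilla. Pulp-restricted genes had more than 50 CPM in every pulp library and more than 20 times the level of every collar library; they are restricted against the collar alone, with medians of 25.9% to 74.4% of the pulp level in the sheaths and the dermal papilla. Tissue-restricted genes exceeded 10 times every library of the other tissues in each library of one tissue.

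Total counts per library ran from 12514383 to 31404619, so that one count was worth 0.0318 to 0.0799 CPM. A fold against a group with 0 counts is a lower bound computed from 3 counts over the group. Where the lower group had 1 to 3 counts the ratio is given with an exact 95% interval from the binomial distribution of its counts. Such bounds and intervals cover counting error only. Replicate libraries of one group were compared gene by gene with a chi-square statistic; its median per gene ran from 4.56 to 34.6, far above sampling noise, and no library was found deposited more than once.

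Tissues of one animal were checked for shared deviations. Over the 30 pairs of tissues within a sex, the correlation across genes of the difference between animal 1 and animal 2 ran from 0.0094 to 0.609 with a median of 0.194, and 25 pairs were over 0.1. The pairing itself comes from the labels, which name the animal of each library. A fit with the animal as a replicate block was run for the comparisons between tissues and for the interaction. No block of animals is possible between the sexes.

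The alternatives planned before the data were examined were DESeq2 1.42.0, RLE in place of TMM, no filter on low counts, a 2-fold minimum (adjusted p of 0.01 for the interaction), only the libraries compared, the replicate block, limma 3.58.1 voom with the animal as a random effect, the mean of the 6 tissue contrasts, and leaving out each library or animal. Alternatives chosen after seeing the data left out 3 libraries that stand apart, summed fewer tissues, or changed the definition of the gene sets. Other versions of the gene lists and of the Z chromosome ratio were not run, for want of names and positions. Other groupings of the libraries were fitted in the same way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

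The fits were tested on simulated negative binomial counts, with means, library sizes and dispersions taken from the real data. A known set of genes was changed, 66 or 67 per fold size, and the others had no difference in the comparison tested. The changed genes were drawn from those with a mean of at least 1 CPM. For the sheaths they also lay within 2-fold of each other in the 2 sheaths. Recovery of genes at lower levels was not tested. For the sex difference in the pulp over 14077 genes, 10.4% of genes changed 2-fold, 70.2% of those changed 4-fold and 80.3% of those changed 8-fold were recovered, with 5 false calls among 112. For the interaction with the change in one tissue alone, recovery was 0%, 29.8% and 57.6%. For the animal sums over 14576 genes it was 31.3%, 86.6% and 100%, with 12 false calls among 157. For the lower against the upper follicle sheath it was 41.8%, 83.6% and 100%, and for the pulp against the other tissues 52.2%, 95.5% and 98.5%. The sheath run gave the 2 sheaths a common mean and kept the other tissues, and the pulp run gave all tissues a common mean. In these 2 runs 10 of 160 and 9 of 173 calls were false. Recovery with deviations shared by the tissues of one bird was not tested. Differences of 2-fold between the sexes in the pulp are thus mostly below what 2 libraries per group could call. The sex difference in the other tissues was not simulated.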

Results

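The transcriptomes of 6 parts of the sickle feather follicle were measured in 2 male and 2 female adult chickens by RNA sequencing. The parts were the lower and the upper follicle sheath (the wall around the feather base), the pulp (the vascular connective core of the growing feather), the collar epithelium (the epithelial ring from which the feather grows), the papilla ectoderm (the epithelium over the papilla) and the dermal papilla (the connective tissue at the base of the follicle). The design asks how the sexes differ in each tissue, and the same libraries show how the tissues differ from each other. Libraries held 12514383 to 31404619 counts, and between 13802 and 15137 of the 17108 genes had at least one count. The papilla ectoderm was the most uneven tissue in depth, from 12514383 counts (female 1) to 31404619 (male 2). It also put the most counts into few genes: its 10 most abundant genes took 34.4% ± 7.67 of all counts (SD, n = 4), against means of 8.53% to 14.2% in the other 5 tissues.

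Tissue set the main structure of the data. The first principal component, with 44.7% of the variance, placed the 4 collar libraries at 174 to 193 and the 4 dermal papilla libraries at -87.2 to -40.4. The second, with 16.8%, separated the pulp (77.3 to 83.4) from the upper follicle sheath (-87.7 to -73.2). For 23 of the 24 libraries the most similar library by Spearman correlation was of the same tissue, and for 16 it was of the same tissue and sex. The exception was the lower follicle sheath of female 1, whose closest library was the dermal papilla of the same bird (rho 0.958). Mean correlations within a tissue were lowest in the papilla ectoderm (0.927) and highest in the upper follicle sheath (0.977). Between tissues, the collar epithelium and the lower follicle sheath were the least alike (mean rho 0.722), and the lower follicle sheath and the dermal papilla the most alike (0.929).

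**Figure D1:**
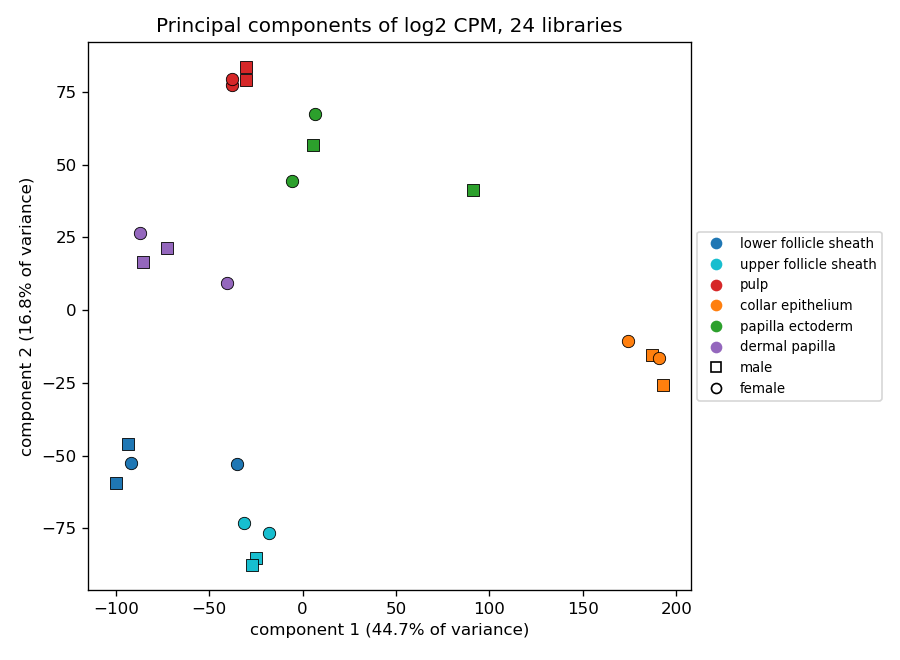
Each point is one of the 24 libraries, placed by its first (x axis, 44.7% of the variance) and second (y axis, 16.8%) principal component of log2 CPM; color gives the tissue and shape the sex. The 4 collar epithelium libraries lie apart at 174 to 193 on the first component, and male 1 of the papilla ectoderm (91.4) lies between them and the other 3 papilla ectoderm libraries.

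By the definition above, 35 genes were female-limited, and the lack of overlap between the sexes in them follows from that choice. Their summed level was 931 to 2272 CPM in the 12 female libraries and 0.12 to 8.78 CPM in the 12 male libraries. The most abundant, ENSGALG00000022674.2, reached 177 ± 96.0 CPM in females (SD, n = 12) and 0.228 CPM in males. In 10 of the 35 genes, all 12 male libraries had 0 counts. Across tissues, the summed level was highest in the collar epithelium, at 2272 and 1590 CPM in the 2 females, against 931 to 1259 CPM in the other 10 female libraries. In males, 10 libraries had 0.975 CPM or less, and the papilla ectoderm had 2.15 CPM (male 1, 30 counts) and 8.78 CPM (male 2, 202 counts). Animals 53 and 52 alone gave 37 such genes, animals 68 and 120 alone also 37, and the 35 were common to both. No gene was limited to males by the same rule.

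**Figure D2:**
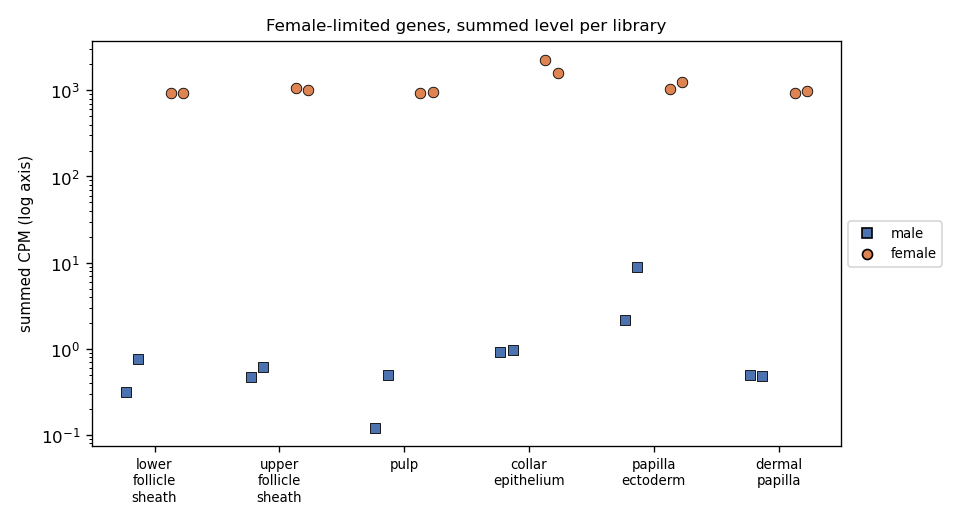
The summed level of the 35 female-limited genes (y axis, CPM, log scale) is plotted for each library by tissue (x axis); squares are male and circles female libraries. All 12 female libraries lie between 931 and 2272 CPM and all 12 male libraries at or below 8.78 CPM, with male 2 of the papilla ectoderm the highest of the males. The genes were chosen for a gap between the sexes in these same libraries.

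Within single tissues, 467 genes differed between the sexes in at least one tissue by edgeR's quasi-likelihood test. Of these, 199 were higher in males in some tissue, 238 were higher in females without being female-limited, and 34 were female-limited; 4 genes count on both sides, called in opposite directions in different tissues. The female-limited genes, chosen for a gap between all female and all male libraries, were called in nearly every tissue (33 of them in all 6). The others were mostly called in a single tissue: 150 of the 199 male-higher and 219 of the 238 female-higher genes. A call in one tissue alone does not show a difference between tissues; that test is given below. Genes called in all 6 tissues and outside the female-limited set numbered 3, named here after their values were seen. ENSGALG00000014661.4 and ENSGALG00000021365.3 were higher in males by about the same amount everywhere, with log2 differences of 0.98 to 1.18 and of 0.85 to 1.12. ENSGALG00000013922.3 was higher in females, with log2 differences, male minus female, of -4.95 (upper follicle sheath) to -8.40 (collar epithelium). Its female level was 974 ± 282 CPM in the pulp, 189 ± 28.7 in the papilla ectoderm and 115 ± 27.8 in the dermal papilla, against 7.68, 1.32 and 2.63 CPM in males (SD, n = 2 per sex). It varied more between the females in the lower sheath (46.8 ± 20.7 CPM), the upper sheath (40.3 ± 31.1) and the collar (16.45 ± 17.3). Males had 0.896, 1.27 and 0.039 CPM there.

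**Figure D3:**
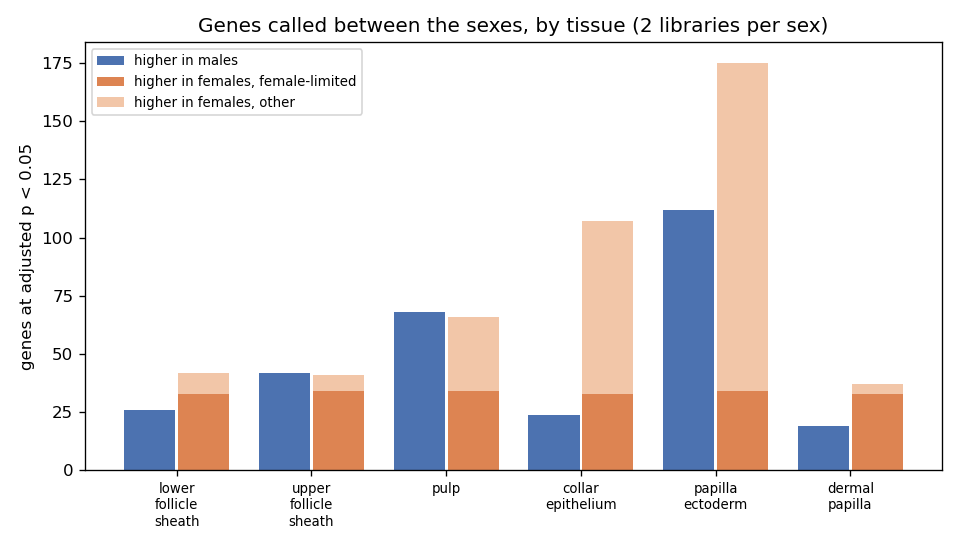
Bars give the number of genes (y axis) at an adjusted p under the threshold in each tissue (x axis), split into genes higher in males, female-limited genes and other genes higher in females. The female-limited part is 33 or 34 genes in every tissue, while the other calls range from 4 to 141 for females and from 19 to 112 for males.

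In the lower follicle sheath 26 genes were higher in males and 42 in females, of which 33 were female-limited. ENSGALG00000009768.4 stood at 58.7 ± 6.19 CPM in males and 7.76 ± 0.20 in females (log2 difference 2.92 ± 0.58 SE, adjusted p = 0.0355). ENSGALG00000028179.1 had 80 counts in the males and 1 in the females, a ratio of 93.5 (95% interval 16.3 to 3740, counting error only). On the female side, ENSGALG00000013922.3 stood at 46.8 ± 20.7 CPM against 0.896 ± 0.37, and ENSGALG00000026514.1 at 3.21 ± 0.97 against 0.135. The 25 collar-restricted genes stood at a median of 9.41% of their collar level in female 1 and at 0.012% to 0.043% in the other 3 libraries. Of the 68 calls 0 were such genes. This says little, since 25 of 14077 genes is a small share and the females differed widely from each other in them. Counts of male-higher and female-higher genes were 147 and 179 by DESeq2 (326 in all), 0 and 11 with the 4 libraries alone, 14 and 31 without male 1, 8 and 33 without male 2, 3 and 48 without female 1 and 7 and 147 without female 2. Named genes lost the call with the 4 libraries alone (adjusted p 0.0523 to 0.331) and with one library left out. ENSGALG00000009768.4 (0.108 to 0.294) and ENSGALG00000028179.1 (0.0633 to 0.262) lost it without any one of the 4. ENSGALG00000013922.3 lost it without male 1 (0.185) or male 2 (0.108), and ENSGALG00000026514.1 without male 1 (0.278), male 2 (0.271) or female 2 (0.0528).

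In the upper follicle sheath 42 genes were higher in males and 41 in females, 34 of these female-limited. ENSGALG00000017183.4 reached 547 ± 178 CPM in males and 41.1 ± 11.7 in females (log2 difference 3.73 ± 0.58 SE, adjusted p = 0.0042). ENSGALG00000028179.1 was again nearly absent from females (99 counts against 1, ratio 102, 95% interval 17.9 to 4076). ENSGALG00000026514.1 was higher in females (251 counts against 2 in males, ratio 122, 95% interval 33.3 to 1010). ENSGALG00000026466.1 stood at 16.4 ± 9.38 CPM in females and 0.431 ± 0.21 in males (adjusted p = 0.0498). The balance moved to 188 male-higher and 77 female-higher genes by DESeq2, 71 and 35 with the 4 libraries alone, 22 and 34 without male 1, 5 and 29 without male 2, 5 and 35 without female 1 and 3 and 37 without female 2. ENSGALG00000026466.1 lost the call with RLE scaling (adjusted p 0.0524), with no filter (0.0529) and without any one library (0.0933 to 0.381). ENSGALG00000028179.1 lost it without male 2 (0.142), female 1 (0.346) or female 2 (0.203). ENSGALG00000017183.4 lost it without female 1 (0.0637) or female 2 (0.165), and ENSGALG00000026514.1 without male 1 (0.0535) or male 2 (0.111).

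In the pulp 68 genes were higher in males and 66 in females, and 32 of the latter were not female-limited. ENSGALG00000007543.4 showed the largest female excess outside that set, at 187 ± 16.0 CPM against 1.09 ± 0.13 in males (log2 difference -7.41 ± 0.86 SE, adjusted p = 0.000165). ENSGALG00000013922.3 followed (log2 difference -6.99 ± 0.96, adjusted p = 0.00108). Among male-higher genes, ENSGALG00000015737.4 stood at 29.1 ± 9.30 CPM against 0.336 ± 0.22, and ENSGALG00000028682.1 at 8.26 ± 1.73 against 0.118 ± 0.065. Most male-higher calls rested on all 4 libraries: male-higher and female-higher counts were 7 and 34 without male 1, 13 and 34 without male 2, 2 and 45 without female 1 and 3 and 40 without female 2. They were 218 and 170 by DESeq2, 350 and 281 with the 4 libraries alone and 144 and 120 without 3 libraries of other tissues that stand apart. ENSGALG00000028682.1 lost the call without any one library (adjusted p 0.128 to 0.353), ENSGALG00000015737.4 without female 1 (0.0849) and ENSGALG00000013922.3 without male 1 (0.0519) or male 2 (0.0526).

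In the collar epithelium 24 genes were higher in males and 107 in females, 74 of these outside the female-limited set. ENSGALG00000024487.2 stood at 9.84 ± 5.14 CPM in females and 0.265 ± 0.012 in males (log2 difference -5.19 ± 1.09 SE, adjusted p = 0.0368). ENSGALG00000013922.3 had 739 counts in females against 2 in males (ratio 416, 95% interval 115 to 3446, counting error only), with 4.18 and 28.7 CPM in the female libraries. ENSGALG00000004526.4 was higher in males, at 13.3 ± 1.46 CPM against 0.484 ± 0.35, and so was ENSGALG00000012290.4, at 6.76 ± 3.93 against 0.398 ± 0.23. Counts depended on single libraries: male-higher and female-higher genes numbered 2 and 35 without male 1, 80 and 151 without male 2, 5 and 51 without female 1 and 914 and 1068 without female 2. They were 275 and 948 by DESeq2, and 134 and 284 without the 3 libraries of other tissues that stand apart. ENSGALG00000004526.4, ENSGALG00000012290.4 and ENSGALG00000024487.2 lost the call without male 1 (adjusted p 0.189, 0.332 and 0.408) or female 1 (0.31, 0.294 and 0.0663), the last also without male 2 (0.0867), and ENSGALG00000013922.3 without male 1 (0.12).

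In the papilla ectoderm 112 genes were higher in males and 175 in females (141 outside the female-limited set). ENSGALG00000002318.4 stood at 220 ± 238 CPM in females and 1.16 ± 1.44 in males (log2 difference -7.45 ± 1.13 SE, adjusted p = 0.00245), whereas ENSGALG00000013922.3 was steadier (189 ± 28.7 against 1.32 ± 0.96). ENSGALG00000012538.4 stood at 179 ± 215 CPM in males and 5.08 ± 3.58 in females, and ENSGALG00000016111.4 at 16.6 ± 22.7 CPM, with 0.573 in male 1 and 32.7 in male 2, against 2 counts in females (ratio of counts 299, 95% interval 82.6 to 2476, counting error only). Of the 141 female-higher calls outside the female-limited set, 6 were among the 78 genes restricted to the pulp against the collar. That is above the share of these 78 among the 14077 genes tested. Of the 112 male-higher calls 0 were such genes. The 78 genes stood at a median of 4.39% of their pulp level in male 1 and at 32.8% to 40.6% in the other 3 libraries. Without that male 157 genes were male-higher and 52 female-higher, 108 of the 209 being among the 287, so the female excess in calls turned; without it and 2 libraries of other tissues the counts were 131 and 46. They also moved without male 2, female 1 or female 2, and were 346 and 504 by DESeq2. With the 4 libraries alone edgeR called 0 genes and put 514 at an unadjusted p under 0.05. That is fewer than the share of 0.05 of 14077 genes expected if no gene differed. ENSGALG00000016111.4 lost the call without male 2 (log2 difference 2.99, adjusted p 0.112), female 1 (0.233) or female 2 (0.0662), and ENSGALG00000012538.4 without male 1 (log2 difference 2.41, adjusted p 0.294), female 1 (0.218) or female 2 (0.144).

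In the dermal papilla 19 genes were higher in males and 37 in females, of which 33 were female-limited. ENSGALG00000008661.3 stood at 817 ± 505 CPM in males and 68.5 ± 1.80 in females (log2 difference 3.58 ± 0.62 SE, adjusted p = 0.0119), and ENSGALG00000002549.4 at 104 ± 25.7 against 15.9 ± 0.094. On the female side, ENSGALG00000013922.3 (115 ± 27.8 CPM against 2.63 ± 0.024) and ENSGALG00000015810.4 (3.19 ± 0.87 against 0.457 ± 0.18) had the largest differences outside the female-limited set. Collar-restricted genes stood at 2.95% of their collar level in female 1 and at 0.023% to 0.026% in the other 3 libraries, and 0 of them were called. This says little, since they are 25 of 14077 genes and the females differed widely from each other in them. The balance turned with DESeq2 (111 male-higher and 89 female-higher genes), and was 3 and 24 with the 4 libraries alone, 1 and 32 without male 1, 21 and 32 without male 2, 2 and 34 without female 1 and 3 and 37 without female 2. ENSGALG00000015810.4 lost the call with no filter (adjusted p 0.0528), with the 4 libraries alone (0.303) and without any one library (0.0833 to 0.586). ENSGALG00000008661.3 and ENSGALG00000002549.4 lost it without male 1 (0.182 and 0.204), female 1 (0.258 and 0.35) or female 2 (0.174 and 0.219), the first also with the 4 libraries alone (0.196). ENSGALG00000013922.3 lost it without male 1 (0.225) or male 2 (0.145).

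Summed over the 6 tissues of each bird, 35 genes were higher in males and 46 in females (edgeR, 2 animals per sex), and 33 of the latter were female-limited. ENSGALG00000014441.4 and ENSGALG00000028913.1, both female-limited, had 0 counts in the male sums and 19.3 ± 1.80 and 10.2 ± 1.002 CPM in the female sums, at least 1825-fold and 972.9-fold higher. ENSGALG00000028682.1 (1.86 ± 0.61 CPM in males, 0.0402 ± 0.024 in females) and ENSGALG00000028564.1 (1.37 ± 0.39 against 0.059 ± 0.0061) were higher in the male sums. For the first, the pulp alone held 521 of the 547 male counts and 8 of the 12 female counts. Both lost the call without female 1 (adjusted p 0.0835 and 0.106) or female 2 (0.0656 and 0.129) and with limma voom (log2 difference 1.97 and 1.60, adjusted p 0.147 and 0.6), and the second with the mean of the 6 contrasts (log2 difference 1.76, adjusted p 1). The balance between the sexes turned with the setting. The mean of the 6 contrasts over 24 libraries gave 572 male-higher and 552 female-higher genes. That fit has no term for the animal and treats the tissues of one bird as independent replicates of a sex, so its counts overstate the evidence. Male-higher and female-higher genes numbered 538 and 296 by DESeq2, 246 and 129 with limma voom and the animal as a random effect, 62 and 55 with no filter, and 149 and 99 with only the upper sheath, pulp and collar in the sums. They were 91 and 52 without male 1, 142 and 123 without male 2, 17 and 63 without female 1 and 11 and 34 without female 2.

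Whether the sex difference itself differed between tissues was tested gene by gene with an F test over the 6 tissues. A single gene passed, ENSGALG00000012327.4 (adjusted p = 0.0495), with 1252 genes at an unadjusted p under 0.05. That is more than the share of 0.05 of 14077 genes expected if no gene differed. The further counts at an unadjusted p under 0.05 below are to be read against the same share of the genes tested. Its log2 difference, male minus female, was -4.25 ± 0.45 (SE) in the collar epithelium (adjusted p = 5.91e-05), -1.47 ± 0.34 in the papilla ectoderm (adjusted p = 0.0398), -1.31 ± 0.33 in the pulp (adjusted p = 0.0922), and between -0.06 and 0.55 in the sheaths and the dermal papilla, the last 4 short of the threshold. The call of this gene rests on single birds and settings: its adjusted p was 1 without female 1, 0.199 without female 2, 0.097 without male 1 and 0.0185 without male 2. It was 0.0613 with no low-count filter and 0.053 with a replicate block for the animal (0 genes each by edgeR, with 1169 and 1738 at an unadjusted p under 0.05). DESeq2's likelihood ratio test called 440 genes, this one included, and edgeR called 2 with RLE scaling, 3 without female 2, 287 without male 2, 0 without female 1 (298 at an unadjusted p under 0.05) and 29 without the 3 libraries that stand apart.

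The tissues differed far more than the sexes. Against the mean of the other 5 tissues, the collar epithelium had 4835 genes higher and 4931 lower, out of 14077. The other tissues had 2886 (papilla ectoderm) to 3315 (upper follicle sheath) genes higher and 2112 (lower follicle sheath) to 2670 (pulp) lower. ENSGALG00000002907.4 and ENSGALG00000027177.1 marked the lower follicle sheath, at 973 ± 861 and 763 ± 403 CPM (SD, n = 4) against means of 0.117 and 0.115 CPM over the other 20 libraries. ENSGALG00000006469.4 (227 ± 147 CPM against 0.219) and ENSGALG00000016682.4 (69.8 ± 39.1 against 0.344) marked the upper follicle sheath. In the pulp ENSGALG00000014144.4 stood at 520 ± 135 CPM against 8.48, and ENSGALG00000027702.1 at 129 ± 32.3 against 1.79. The collar epithelium was marked by ENSGALG00000027163.1 (466 ± 37.8 CPM against 4.26) and ENSGALG00000013664.2 (283 ± 38.6 against 1.75). ENSGALG00000007367.4 reached 4902 ± 2477 CPM in the dermal papilla against 72.1, and ENSGALG00000021303.2 39.5 ± 22.9 against 0.824. In the papilla ectoderm ENSGALG00000026297.1 stood at 96.3 ± 48.7 CPM against 1.103 and ENSGALG00000026199.1 at 1.17 ± 1.16 against 0.0222. Their fitted log2 differences, 7.28 and 5.88, were the smallest of these 12 genes. Genes restricted to the pulp against the collar stood at 4.39% (male 1) to 40.6% (female 1) of their pulp level in this tissue. The effect of dermal tissue on its counts was not tested. All 12 genes passed the threshold by edgeR, with adjusted p from 3.12e-11 to 4.13e-05. With a 2-fold minimum the counts were 6023 for the collar epithelium and 2324 to 3020 for the others, and leaving out a bird lowered some by more than 1.5 times. They fell to 2282 without female 2 and 3273 without male 1 in the lower sheath, 3314 and 3285 without female 1 and female 2 in the upper sheath, 3426 and 3623 in the pulp, 3577 and 2837 in the dermal papilla, and 2131 without female 2 in the papilla ectoderm. The balance of higher and lower genes turned for the collar epithelium with no filter (5010 and 4812), without each bird (4083 and 4029 without female 1 to 4475 and 4066 without male 2) and without the 3 libraries that stand apart (5137 and 4899), and for the papilla ectoderm with no filter (2528 and 2542) and without male 2 (2265 and 2783).

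Neighbouring parts of the follicle were compared in pairs. The lower follicle sheath had 739 genes higher and 1040 lower than the upper follicle sheath. ENSGALG00000027177.1 stood at 763 ± 403 CPM in the lower and 0.0592 ± 0.035 in the upper sheath, ENSGALG00000014848.4 at 49.7 ± 47.3 CPM against 0 counts (at least 1744-fold higher), ENSGALG00000006469.4 at 0.107 ± 0.10 against 227 ± 147 CPM, and ENSGALG00000016682.4 at 1 count against 7183 (ratio 6979, 95% interval 1252 to 275700). Without female 1, female 2, male 1 and male 2 the total of 1779 genes fell to 904, 692, 956 and 985. The balance turned without male 1 (502 higher and 454 lower), without male 2 (505 and 480) and with DESeq2 (1350 and 1225). The papilla ectoderm had 4499 genes higher and 3661 lower than the collar epithelium. Of its named genes, ENSGALG00000017267.3 stood at 135 ± 210 CPM, from 0.43 to 443 over the libraries, against 2 counts in the collar (ratio 5040, 95% interval 1395 to 41630), and lost the call without male 2 (log2 difference 7.83, adjusted p 0.142). ENSGALG00000004393.4 stood at 35.1 ± 38.6 CPM, from 0.43 to 76.99 over the libraries, against 2 counts (ratio 1544, 95% interval 427 to 12750). ENSGALG00000008048.4 (33.3 ± 7.18 CPM in collar) and ENSGALG00000021274.2 (23.1 ± 13.5 CPM in collar) had 2 and 1 counts in the papilla ectoderm (ratios 1079, 95% interval 298 to 8912, and 1621, 95% interval 291 to 64070). Pulp-restricted genes, low in the collar by definition, stood at 0.684% to 3.125% of their pulp level there. In the papilla ectoderm they stood at 4.39% in male 1 and at 32.8% to 40.6% in the other libraries. The effect of dermal tissue on the 4499 and 3661 genes was not tested. The dermal papilla had 1951 genes higher and 1740 lower than the pulp. ENSGALG00000007367.4 stood at 4902 ± 2477 CPM in the dermal papilla and 5.12 ± 5.75 in the pulp, and ENSGALG00000007226.4 at 356 ± 134 against 0.160 ± 0.10. ENSGALG00000011345.4 (5.79 ± 1.29 CPM in pulp) and ENSGALG00000027809.1 (1.01 ± 0.36) had 0 counts in the dermal papilla, at least 205-fold and 35.6-fold lower. The 3691 genes of this pair fell to 1877 without female 1 (919 higher and 958 lower) and 1356 without female 2. The balance also turned with RLE scaling (1772 and 1888), a 2-fold minimum (1161 and 1254), DESeq2 (2061 and 2216), the 8 libraries alone (2618 and 2942) and without 3 libraries that stand apart (1972 and 2106). For papilla ectoderm against collar it turned without male 2 (3016 and 3066), and the 8 libraries alone gave 5381 genes.

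**Figure D4:**
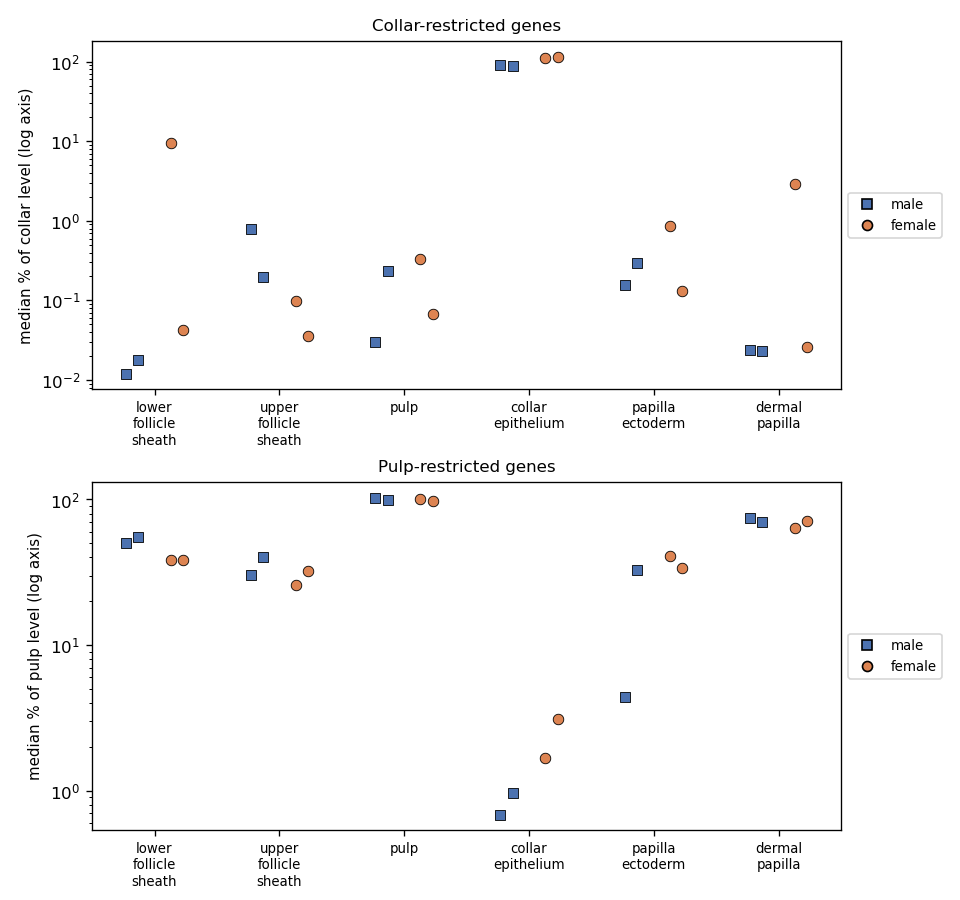
The median level of 25 collar-restricted genes (upper panel, percent of the collar level, log scale) and of 78 genes restricted to the pulp against the collar (lower panel, percent of the pulp level, log scale) is plotted per library by tissue; squares are male and circles female. Female 1 stands at 9.41% in the lower follicle sheath and 2.95% in the dermal papilla in the upper panel, and male 1 at 4.39% in the papilla ectoderm in the lower panel, each away from the other 3 libraries of its tissue.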

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

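The tests that weigh explanations for the 3 patterns of collar-restricted, pulp-restricted and female-limited genes were chosen after the result was seen, as were these gene sets. A gap test on 11 measures in each of the 6 tissues, 66 groups of 4 libraries, singled out 7 values; chance alone singles out about 1 group in 20.

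Female 1 stood away from the other 3 lower follicle sheath libraries on component 1 (-35.2 against -100.0 to -92.0), in its mean correlation with the tissue (0.949 against 0.961 to 0.963) and in collar-restricted genes (9.41% of collar against at most 0.043%), which in its dermal papilla stood at 2.95% against at most 0.026%. Genes of like level in collar and tissue shifted between female 1 and female 2 by a median log2 of -0.068 (lower sheath, SD 0.40) and -0.005 (dermal papilla, SD 0.39). TMM scaling holds most genes near 0, so these shifts alone decide nothing. The collar-restricted genes differed by a median log2 of 7.81 and 4.77 in the same libraries. Depth or normalization, as a factor common to all genes, is argued against by that contrast. For a sex difference, the test counted collar-restricted genes over 2 times higher in female 2 than in both males. These were 32% in the lower sheath and 8% in the dermal papilla, and the test did not decide. Female 2 stood at 0.452% and 0.87% of female 1, values computed after that result was seen that restate the gap and are no further test. A sex difference shared by both females is argued against as the source of this gap, while a smaller sex difference stays open. Collar tissue in both libraries of female 1 remains a candidate explanation. Of the 25 genes, 96% in the lower sheath and 100% in the dermal papilla were over 2 times higher in female 1 than in female 2. These shares show that nearly all the genes took part. They otherwise restate the gap in the same genes and are no separate support for collar tissue. A change within female 1 as a bird stays open. In its pulp 56% of the genes (median log2 1.08) and in its upper sheath 40% (0.80) were also over 2 times higher than in female 2. Against the males the upper sheath of female 1 was not raised, at a median of 0.097% of collar against 0.793% (male 1) and 0.199% (male 2). Its pulp stood at 0.33% against 0.03% and 0.233%.

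Male 1 stood away from the other 3 papilla ectoderm libraries on component 1 (91.4 against -5.73 to 6.41). Of 78 genes restricted to the pulp against the collar, 84.6% were over 2 times lower in it than in each of the others. This share largely restates the gap in their median level, 4.39% of pulp against 32.8% to 40.6%. Less pulp or other dermal tissue in this library is a candidate explanation, for which the share is no separate support. The 3998 genes of like level in pulp and collar shifted by a median log2 of 0.182 (SD 0.88), in the other direction. TMM scaling holds most genes near 0, so this shift alone decides nothing. Depth or normalization, as a factor common to all genes, is argued against by the contrast between the 2 gene sets. A sex difference is argued against by male 2, in which 8.97% of the genes were over 2 times lower than in both females. Further gene sets were chosen to be several times higher in a dermal tissue than in every collar library. Those also higher in the dermal papilla than in the pulp were lower in it as well (76 genes, median log2 -1.79, 32 of them over 2 times lower than in each of the others). The same held for those higher in the pulp than in the dermal papilla and sheaths (19 genes, median log2 -1.45, 9 of them). It also held for those higher in the lower sheath than in the pulp (126 genes, median log2 -1.08, 50 of them). Which dermal tissue differs is thus left open, and with it a real difference of this bird's papilla.

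Male 2 of the papilla ectoderm held 202 counts of female-limited genes, 0.762% of the mean female papilla ectoderm level. Reads of similar genes misassigned in every male stay open: the level was 4.09 times that of male 1 in the same tissue, 21 of the 35 genes were highest in this library among the 12 male libraries, and the gene shares differed from the pooled other 11 (permutation p = 1e-04, the smallest that 10000 permutations can give). These values go against it, but the 95% interval (2.78 to 6.22) and the p cover counting error only, and 1 library stands against 1. Reads from female papilla ectoderm are a candidate explanation, since the counts followed female 2 of that tissue over the 35 genes (Pearson r = 0.962 across genes, which are not independent replicates; 0.344 with the pooled males), the highest of the 12 female libraries. Whether they entered as tissue, in the library preparation or in sequencing was not tested. No biological explanation was tested.

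Female 1 of the collar epithelium had the largest share of counts in the most abundant gene (2.998% against 1.74% to 1.84%) and in the 10 most abundant (13.2% against 9.75% to 9.83%). For the sex difference of ENSGALG00000012327.4, edgeR's interaction test across tissues gave an adjusted p of 0.0495, which rose to 0.053 with a replicate block, 0.0613 with no filter, and 1, 0.199 and 0.097 without female 1, female 2 and male 1.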

How the results depend on the processing

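Alternatives that left out 3 libraries or used fewer tissues, and all those for the female-limited genes and the genes apart in all 6 tissues, were chosen after seeing the data; the others were planned. Of 174 alternative counts of called genes, 101 stayed within 1.5 times the reported count, 47 were lower and 26 higher. Of 546 alternative values for the 53 named gene results, 456 kept the call, 90 lost it and 0 changed sign. Where a count moved, the cause was not tested, except that a fold minimum lowers counts by construction; leaving out a library lowered some counts and raised others.

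RLE scaling and no filter moved the interaction by over 1.5 times, to 2 and 0 genes; with no filter the collar had 92 genes between the sexes and the animal sums 117 (62 male-higher and 55 female-higher, the reported balance turned). A 2-fold minimum gave 2701 (lower sheath), 2808 (upper sheath), 3020 (pulp), 6023 (collar), 2324 (papilla ectoderm) and 2652 (dermal papilla) genes against the other tissues, 5419 for papilla ectoderm against collar and 2415 for dermal papilla against pulp; an adjusted p of 0.01 left 0 interaction genes by edgeR (1252 at an unadjusted p under 0.05). DESeq2 called more genes between the sexes, 326, 265, 388, 1223, 850 and 200 in the 6 tissues in the same order, 440 for the interaction and 834 over all tissues. Only the libraries compared gave 11 (lower sheath), 631 (pulp), 0 (papilla ectoderm, edgeR, 514 at an unadjusted p under 0.05) and 27 (dermal papilla) genes between the sexes. The 514 are fewer than the share of 0.05 of 14077 genes expected if no gene differed. The same setting gave 5381 genes for papilla ectoderm against collar and 5560 for dermal papilla against pulp. Over all tissues, voom with the animal as a random effect (correlation 0.132) gave 375 genes, and sums of upper sheath, pulp and collar gave 248. The mean of the 6 contrasts gave 1124, but without a term for the animal it treats the tissues of one bird as independent. The replicate block ended the one interaction call (0 genes) and moved no other count by over 1.5 times. Without the 3 libraries that stand apart the sexes differed in 264 (pulp), 418 (collar) and 177 (papilla ectoderm) genes, and 29 passed for the interaction.

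Leaving out one library of a tissue, the lone library then being assumed to vary like the other groups, gave 41 to 154 genes between the sexes in the lower sheath, 34 to 56 in the upper sheath, 41 to 47 in the pulp, 37 to 1982 in the collar, 63 to 2831 in the papilla ectoderm and 33 to 53 in the dermal papilla. Leaving out one bird gave 45 to 265 genes over all tissues and 0 to 287 for the interaction, whose gene kept its call only without male 2. Against the other tissues it gave 2282 to 4180 (lower sheath), 3285 to 4449 (upper sheath), 3426 to 4521 (pulp), 8112 to 9129 (collar), 2131 to 5048 (papilla ectoderm) and 2837 to 4180 (dermal papilla), with the lowest values without female 2, or female 1 for pulp and collar. The pairs gave 692 to 985 (sheaths), 5827 to 7514 (papilla ectoderm and collar) and 1356 to 2767 (dermal papilla and pulp).

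The set of 35 female-limited genes numbered 35 or 36 under each of the 8 alternatives tried. Genes apart in all 6 tissues were 125 (males higher) and 83 (females higher), 111 and 81 with RLE, 146 and 80 with no filter, and 369 and 483 when only upper sheath, pulp and collar had to part. Alternatives of the gene lists and of the Z chromosome ratio were not run. With 2 birds per sex, 10.4% of simulated 2-fold changes in the pulp were recovered, so a gene not called may still differ.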

Other observations

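Counts of called genes over other groupings of the libraries were planned; the other tests and the gene sets were chosen after the values were seen. Genes found in one tissue at more than 10 times the level of every library of the others numbered 47 in the lower follicle sheath (median 65.7 CPM), 11 in the collar epithelium (median 271 CPM), 3 in the pulp, 1 in the upper follicle sheath, and 0 in the papilla ectoderm and the dermal papilla. Without the 3 libraries that stand apart, among them the lower follicle sheath of female 1 with collar-restricted genes at 9.41% of collar, the collar epithelium had 37 such genes and the lower follicle sheath 60, and the other counts were the same. The 25 collar-restricted genes were also low in the papilla ectoderm, at a median of 0.133% to 0.87% of the collar level.

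Calls of a sex difference were shared between tissues by a minority of the called genes. In simulation 10.45% of 2-fold sex differences in the pulp were recovered. A missing call therefore does not show that a difference is absent from a tissue. Outside the female-limited set, 4 genes were called in opposite directions in different tissues, and 68 of 433 called genes were called the same way in 2 or more tissues and 13 in 4 or more. The pulp and the papilla ectoderm shared 30 male-higher genes, where independent lists would share 0.54, and the same 4 birds stand behind every tissue. The log2 differences of the tissues correlated with a median r of 0.217 across genes (15 pairs of tissues), and with 0.188 and 0.182 when the 4 birds were paired in the other 2 ways. The median covariance was 0.164 against 0.0636 and 0.0919. The correlation between tissues was thus nearly as high for groupings that do not follow sex, and the covariance lower. Shared calls were fewer in those 2 pairings. Of 0 and 31 genes called in any tissue, 0 and 1 were called the same way in 2 or more tissues.

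Other groupings of the libraries were fitted to the same genes, with 2 groups per fit. For a tissue against the rest, 100 groupings of 4 against 20 were counted, the real one included. The collar epithelium gave 7873 genes and was matched by 1 grouping, itself, the highest other giving 3857. The lower sheath (262), upper sheath (859), pulp (1174), papilla ectoderm (1150) and dermal papilla (278) were each matched by 4 groupings, themselves included. All 6 met the criterion set before the data were examined, fewer than 5 of 100 groupings. Most of these groupings did not take a library from each bird as the real ones do. The 2-group fits also gave other counts than those reported above. The criterion thus excludes chance for free groupings of libraries alone. The 3 others that matched these 5 tissues took 3 of the 4 collar libraries, which points to the collar as the main structure of the samples. The highest of the rest gave 29 genes. Of the 13 groupings with one library per bird, as in the real ones, 2 reached the counts of these 5 tissues, the real one and one with 3 collar libraries (2027 genes), and 1 that of the collar; 13 are too few for a share under 0.05. For pairs of tissues, 35 groupings of 8 libraries were run, and 1, the real one, gave as many, which met the criterion set before the data were examined. It gave 1814 genes for the sheaths (highest other 177), 5387 for papilla ectoderm and collar (26) and 4960 for dermal papilla and pulp (113). Most of the 35 put both libraries of some bird on the same side, unlike the real one. Chance is thus excluded for free groupings alone. Of the 8 that part every bird, the others gave at most 0 genes, and 8 are too few for a share under 0.05.

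For the sexes, 3 pairings of the 4 birds are too few for a share under 0.05. The real pairing gave 68, 83, 134, 131, 287 and 56 genes in the 6 tissues, 81 over all tissues and 1 for the interaction, and in each case 1 of the 3 pairings gave as many. The highest other counts were 1, 2, 0, 0, 29 and 0 in the tissues and 0 for both remaining tests.

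In 125 genes both males lay above both females in each of the 6 tissues, and in 83, including the 35 female-limited, below them, 208 genes in both directions. The other 2 pairings of the birds parted 9 and 77 genes in both directions. In one tissue, 33.3% of genes part by chance in either direction. The median male excess of the 125 genes was 0.77 on the log2 scale (interquartile range 0.61 to 0.91), and 0.62 (collar epithelium) to 0.89 (papilla ectoderm) in single tissues. In birds males carry a pair of Z chromosomes and females one Z and one W. A candidate explanation is 2 gene copies in males against 1 in females, which asks for an excess of up to 2-fold. This held for 84% of the 125 genes but also for 83.1% of the 77 genes that part animals 53 and 120 from 68 and 52 (Fisher's exact test, two-sided, p = 1, genes not being independent), so the share within 2-fold does not tell a dose effect from a difference between birds. Other values differed more: the median size was 0.77 in the 125 genes and 0.57 in the 77, and of the 48 female-higher genes outside the female-limited set 39.6% lay within 2-fold (median log2 -1.07). Positions of the genes were not used here, and the question stays open.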
